A study of Mus musculus with 2 samples.

How the data were processed

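H3K36me3, the trimethylated form of lysine 36 of histone H3, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse forebrain on postnatal day 0. The design has 1 group with 2 biological replicates. Per the labels, replicate 1 came from the forebrains of 15 pooled mice, replicate 2 from pooled mice whose number the labels leave open, and both pools held male and female tissue of mixed B6N substrains. Replicate 2 combined 2 technical replicates run on different sequencer models, so replicate and sequencing run cannot be separated. Fragment sizes in both libraries ranged from 300 to 500 bp per the labels. No other tissue, age, mark or treatment was compared.

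The authors deposited 4 peak lists on the mouse genome build mm10: the peaks of each replicate, the peaks of both replicates pooled, and a replicated list that, per the file records, was derived from the replicates' lists and the pooled list. The peak caller, the aligner and their versions are not given in the sources used here. Per the file records each of the first 3 lists was made from alignments together with further files, and the control libraries themselves were not used here. Every list holds, for each peak, a score from the authors that is scaled within the list, an enrichment ratio over control, and the −log10 p and −log10 q that the authors' caller gave. The deposited ratio and −log10 p values served here to describe, rank or filter peaks within a list, and the deposited score was not needed for any comparison. The lowest deposited −log10 p lay between 2.01 and 2.04 in all 4 lists.

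Peak lists hold no reads, and the number of reads per replicate is not given in the sources used here, so depth is unknown. The deposited enrichment ratios were not continuous. In the list of replicate 1, 68.3% of peaks lay within 1% of a step of a whole multiple of 0.237. The step was 0.318 in replicate 2 (67.8% of peaks) and 0.166 in the pooled list (62.9% of peaks), where evenly spread values would put 2% of peaks that close. Each step is the smallest difference between the ratios of such peaks.

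Coordinates were compared with GENCODE release M21 on GRCm38, the assembly that mm10 names. All peaks and genes ended within the lengths of the GRCm38 chromosomes. Chromosomes 1 to 19, X and Y were used, and peaks on scaffolds were counted separately. Gene bodies ran from annotated start to annotated end, and 21765 protein-coding genes of at least 500 bp were kept. A gene was called marked when peaks of the authors' replicated list covered at least 10% of its body. The replicated list holds intervals of the pooled list, so it can cover more of a gene than either replicate's list. Feature classes were assigned in the order gene start within 1 kb, coding exon, 5' UTR, 3' UTR, rest of protein-coding genes, other genes. Exon to intron ratios used the union of annotated exons of marked genes with at least 2 exons.

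The overlap of the replicates and the location of peaks were compared with 1000 circular shifts of the peaks within each chromosome, which keep peak widths and spacing. The smallest permutation p that these shifts can give is 0.000999 one-sided and 0.001998 two-sided. The profile along genes used 20 equal bins in marked genes of at least 10 kb, with 500-bp bins over 5 kb on each side. For 28 gene lists, the median coverage of the replicated list was ranked among 10000 random lists of the same size matched on gene length in 20 bins. A list stood apart above percentile 97.5 or below percentile 2.5. These percentiles describe these libraries and are not p-values, because genes are not replicates. Of the 23 imprinted genes written down, 17 are annotated as protein-coding, and of 9 genes that escape X inactivation or lie on the Y, 8 are. All members of the other lists matched.

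Gene lists, tests and alternatives were fixed before the data were examined. So was the rule for genes named in the text, namely the 10 genes with the most covered bases, genes under the 10 replicated peaks of highest enrichment, and the 2 highest and 2 lowest members of each list with ties broken by symbol. The rule also took the 5 marked genes with the largest replicate difference in each direction, and Setd2, Foxg1 and Alb. Values for replicates are given as mean ± SD with n = 2, and intervals of shares are 95% Wilson intervals that cover counting error only. With 2 replicates in 1 group, no test between samples was possible.

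Alternatives were a −log10 q minimum of 2, the 50000 strongest peaks of each list, each replicate's list alone, coverage minimums of 5% and 20%, overlap over 50% of a peak's length, all annotated genes, genes free of overlap with other genes, bases in no other gene (in genes with at least 500 bp of them), gene ends trimmed by 2 kb, first exons left out, means in place of medians, no length matching, and shifts confined to gene bodies. Leaving out first and last exons together, asking for 50% of a pooled peak in both replicates, and the X to autosome ratio of each replicate were chosen after seeing the data. The procedures were tested on simulated data. A simulated coverage ratio of 2 between gene ends came back as 1.92 over 2000 genes, a simulated shared fraction of 0.6 as 0.597 over 155017 peaks, and 3% of random lists of 20 genes fell outside the limits where 5% would by chance.

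For the closing tests, 31-mers were sampled at 200 positions per gene and 20 per peak and counted on both strands of the GRCm38 chromosomes, and marked genes were tiled with 100-bp windows. A set of 11 families of general complexes with 834 genes was written down before its test. Interval arithmetic was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.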

Results

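ChIP-seq of H3K36me3, a histone mark laid down by Setd2 along transcribed genes, was available for the forebrain of newborn mice on postnatal day 0 as 2 biological replicates of 1 group. The list of replicate 1 held 155034 peaks over 83.8 Mb, with a median width of 369 bp. The list of replicate 2 held 201338 peaks over 80.4 Mb, with a median width of 285 bp. Across the replicates the covered length was 82.1 Mb ± 2.42 (SD, n = 2), or 3.01% ± 0.0887 of the chromosomes. The pooled list held 190756 peaks over 111 Mb. The authors' replicated list held 104188 peaks over 88.0 Mb, with a median width of 585 bp and a median enrichment over control of 3.79. Setd2 itself, on chromosome 9 from 110532597 to 110618633, had 27.9% of its body covered by replicated peaks. Alb, a liver gene on chromosome 5 from 90460897 to 90476602, had 0% covered in either replicate and in the replicated list.

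The first comparison asked how far the replicates marked the same places. Of the bases in either replicate's peaks, 42.1% were shared, a length of 48.6 Mb. Of the peaks of replicate 1, 70.8% touched a peak of replicate 2, and of the peaks of replicate 2, 63.0% touched a peak of replicate 1. Across protein-coding genes, coverage of the gene body correlated between the replicates with Pearson r = 0.955 and Spearman rho = 0.939, and among marked genes with r = 0.873 and rho = 0.869. These correlations run across genes, which are not independent replicates. Circular shifts of replicate 2 gave a mean of 1.84% shared bases and a maximum of 3.34%, so the observed value was 22.9-fold above chance (one-sided permutation p = 0.000999, the smallest the shifts can give). With shifts confined to gene bodies, the mean of the shifts rose to 4.16% and the excess fell to 10.3-fold.

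Among marked genes, the largest differences between replicates were in short genes. Ufsp1, a protease that matures the modifier Ufm1, spans 1037 bp on chromosome 5 and had 74.2% of its body covered in replicate 2 and 14.0% in replicate 1. Leap2, a peptide hormone gene of 990 bp on chromosome 11, had 49.3% covered in replicate 2 and 0% in replicate 1, and Tnfrsf4, Gm4707 and Mcts2 also had more coverage in replicate 2. In the other direction, Tstd1, 1481 bp long on chromosome 1, had 91.1% covered in replicate 1 and 17.6% in replicate 2, followed by Gpbar1, Ankrd49, Lsm3 and Mdp1. In Lsm3, which encodes a component of U6 snRNP, coverage was 66.3% in replicate 1 and 31.3% in replicate 2. Among all marked genes the median difference between replicates was 5.61 percentage points.

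The replicated list was then set against the pooled list from which its intervals come. It kept 104184 of 190736 pooled peaks on the chromosomes, or 54.6% (95% Wilson interval 54.4 to 54.8%). Kept peaks had a median width of 585 bp, against 232 bp for those not kept, and a median enrichment of 3.79 against 2.73. With pooled peaks ordered by −log10 p in 10 equal groups, the kept share was 5.82% in the weakest group and 99.9% in the strongest. Of the kept peaks, 87.8% touched a peak in each replicate, as did 2.15% of those not kept. Asking instead for 50% of a pooled peak's length in the peaks of each replicate left 36.6% of pooled peaks.

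Where the mark lay was asked next. Of the bases in replicated peaks, 95.3% fell in protein-coding gene bodies, and 94.6% ± 0.732 (SD, n = 2) did so in the replicates' own lists. Coding exons held 12.04% of the peak bases and 3' UTRs 7.60%, while introns and other parts of coding genes held 75.2%. The 2 kb around gene starts held 0.40%, and sequence outside all annotated genes 3.91%. Over the replicates these shares were 11.7% ± 0.416 for coding exons, 7.25% ± 0.212 for 3' UTRs, 0.421% ± 0.0794 around gene starts and 4.43% ± 0.582 outside genes (SD, n = 2 each).

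Circular shifts placed 42.2% of peak bases in protein-coding genes on average and at most 46.4%, so the observed share was 2.26-fold higher (two-sided permutation p = 0.001998, the smallest the shifts can give). Coding exons were 8.79-fold above the shifts, 3' UTRs 5.82-fold and introns 1.957-fold. Gene starts stood at 0.235 and sequence outside genes at 0.0779 of the shifts' share. All of these reached the same smallest permutation p. 5' UTRs outside the gene start windows held 0.107% of peak bases, 1.25-fold above the shifts (two-sided permutation p = 0.018).

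**Figure D1:**
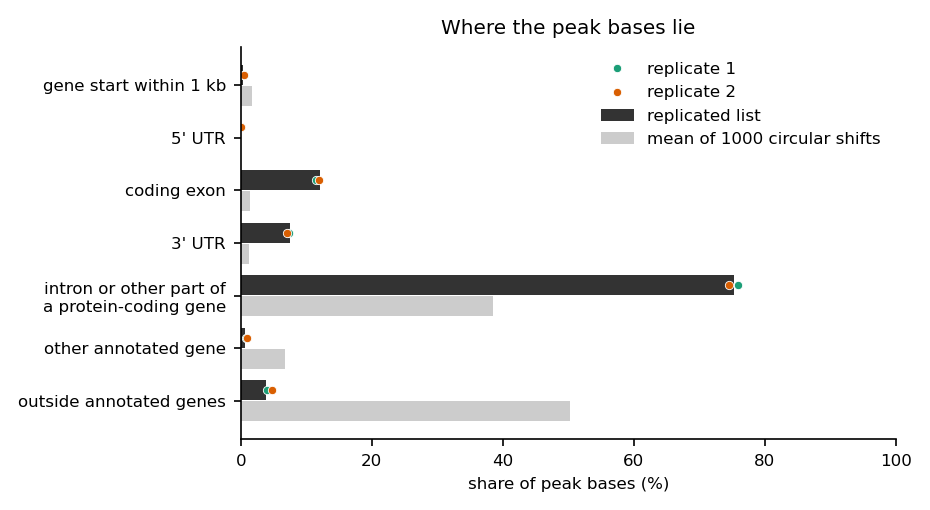
Share of peak bases, in percent, in each class of sequence, with bars for the authors' replicated list and for the mean of 1000 circular shifts and points for the 2 replicates. Coding exons held 12.04% of replicated peak bases against 1.37% in the shifts, and sequence outside annotated genes 3.91% against 50.3%.

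Along genes, coverage rose from start to end. In 5535 marked genes of at least 10 kb, replicated peaks covered 1.41% of the first of 20 bins, 42.0% of bin 11 and 58.0% of bin 18, and then 50.5% of the last bin. Beyond the gene end, coverage was 41.1% in the first 500 bp and 14.1% at 5 kb, and in the last 500 bp before the gene start it was 0.811%. Mean coverage was 23.4% upstream of the genes' midpoints and 50.8% downstream, a ratio of 2.17, and 88.5% of the genes had the higher value downstream. The ratio was 2.09 in replicate 1 and 2.11 in replicate 2. Circular shifts gave a mean ratio of 1.00 and a maximum of 1.36 (two-sided permutation p = 0.001998).

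**Figure D2:**
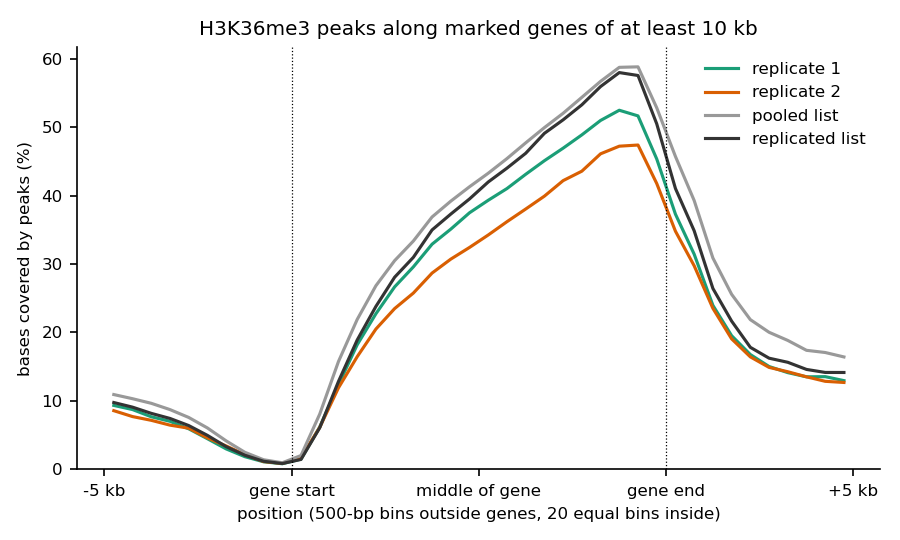
Bases covered by peaks, in percent, along marked genes of at least 10 kb, with 1 line per peak list over that list's own marked genes, 20 equal bins within genes and 500-bp bins over 5 kb on each side. Coverage in the replicated list was lowest beside the gene start (0.811%) and highest in bin 18 of the gene body (58.0%).

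Pooled over marked genes, exon bases were covered more than intron bases. Genes with more intron bases weigh more in the intron share, and exons and introns were not compared gene by gene. Replicated peaks covered 54.6% of exon bases and 28.4% of intron bases in 7187 marked genes with introns, a ratio of 1.92. Each replicate's values were taken over the genes marked by its own list, 7141 in replicate 1 and 7356 in replicate 2. Replicate 1 covered 49.5% of exon and 27.3% of intron bases, and replicate 2 covered 46.3% and 23.8%. Over the replicates the ratio was 1.88 ± 0.0960 (SD, n = 2). No test was applied to this ratio, which rests on 2 replicates.

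At the level of whole genes, 7242 of 21765 protein-coding genes (33.3%) were marked, and 11554 had no replicated peak. The replicates' own lists marked 7316.5 ± 166 genes (SD, n = 2), with 6786 marked in both, 413 in replicate 1 alone and 648 in replicate 2 alone. Genes of 20 to 100 kb were marked most often, at 43.7%, followed by those of 5 to 20 kb at 36.9%. The share was 15.6% under 5 kb and 18.1% above 100 kb. Of the marked genes, 2036 had at least 50% of the body covered.

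The genes with the most covered bases were long. Ubr4, a ubiquitin ligase on chromosome 4 from 139352609 to 139489588, had 112901 bp or 82.4% of its body covered, and 75.0% ± 3.73 (SD, n = 2) over the replicates. Vps13d on chromosome 4, a lipid transfer protein gene, had 49.7% covered, and Macf1 on chromosome 4, which links microtubules and actin, 32.7%. Hectd4 on chromosome 5 had 62.9% covered, Wdfy3 on chromosome 5, an autophagy adaptor, 44.6%, and Fry on chromosome 5 23.9%. Clasp1 on chromosome 1, which binds microtubule ends, had 39.5% covered and Trio on chromosome 15, an exchange factor for Rho proteins, 31.7%. Their replicate SDs ranged from 0.52 for Trio to 5.41 for Macf1. The 2 other genes of this rank, Gm20388 on chromosome 8 with 481035 covered bp and Fgfr2 on chromosome 7 with 133103, have annotated spans of 4434882 and 2960900 bp that run across neighbouring genes. Of their bases outside other genes, 0.75% and 0.62% were covered.

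Of the 10 replicated peaks of highest enrichment, 7 lay in genes for zinc finger proteins, a large family of DNA-binding proteins. The highest enrichment in the replicated list, 11.6, was a peak of 6948 bp in Zfp606 on chromosome 7 from 12486025 to 12492972, of which 87.9% was intron and 12.1% coding exon. A peak in Serinc1 on chromosome 10 from 57522359 to 57523299 reached 10.3, over coding exon and intron. Peaks in Zfp712 on chromosome 13 (67039927 to 67042211, coding exon and 3' UTR) and Zfp157 on chromosome 5 (138455446 to 138458972, 49.1% of it 3' UTR) reached 10.1 and 9.96. Others of the 10 lay in 2610008E11Rik, Zfp354c, Zfp2, Rbm5 and, as a pair of neighbouring peaks, Zfp810. Zfp606 had 81.3% of its body covered and 76.5% ± 9.90 over the replicates (SD, n = 2). Rbm5, an RNA-binding splicing regulator, had 77.3% and 71.3% ± 10.2, while Serinc1 had 30.7% and 27.6% ± 7.60.

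Lists of genes that most cells use were covered highly. Of 39 proteasome genes, 31 were marked, with a median coverage of 46.7%. Psmc1 on chromosome 12 (100110154 to 100123405) had 81.1% covered and 72.3% ± 5.30 over the replicates, and Psmc4 on chromosome 7 had 81.0% and 67.5% ± 14.4 (SD, n = 2). Psma8 and Psmb10, a testis subunit and an immune-type subunit, had 0%. Of 40 splicing factor genes, 33 were marked at a median of 38.8%, led by Sf3a1 on chromosome 11 at 89.3% and Hnrnpul1 on chromosome 7 at 84.8%. Hnrnpa0 and the X-linked Hnrnph2 had 0%, although Hnrnpa0 had 6.87% in replicate 2. Of 79 cytosolic ribosomal protein genes, 60 were marked at a median of 37.5%, led by Rps3 at 77.9% and Rps19 at 73.6%, both on chromosome 7. Rpl10 on the X and Rpl10l had 0%.

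Genes that act in H3K36 methylation were also covered highly, with 18 of 21 marked at a median of 34.0%. Kdm4a, a demethylase on chromosome 4 from 118136957 to 118180043, had 87.0% covered and 77.5% ± 5.06 over the replicates (SD, n = 2). Setd2 had 27.9%, Kdm4c 6.60% and Phf19, a Polycomb subunit that binds the mark, 0%. Brpf1 had 74.0%, all of it in bases shared with another annotated gene. Of 391 numbered zinc finger genes, 251 were marked and 84 had no peak, at a median of 19.7%. In those 84, a median of 53.0% of sampled 31-mers occur once in the genome, against 91.0% for the list, so a value of 0% there cannot be read as absence of the mark. Zfp869 on chromosome 8 (88.9%) and Zfp335 on chromosome 2 (84.2%) led the list, and Zfp114 and Zfp119b had 0%, the latter with 2.01% in replicate 2.

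These 5 lists lay at percentile 100 among the random lists. Over the replicates, the SD of their medians ranged from 2.25 for zinc finger genes to 6.16 for splicing factor genes, less than their distance from the random medians, which lay between 0% and 3.07%.

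Coverage of single pan-neuronal genes ranged from 0.03% to 85.4%. Of 20 such genes, 10 were marked in the replicated list, 8 in replicate 1 and 6 in replicate 2. Their median was 7.52% (7.47% ± 0.145 over the replicates, SD, n = 2), and none lacked a peak. Nsg1, an endosomal protein of neurons on chromosome 5 from 38137192 to 38159907, had 85.4% covered, and Tubb3, the neuronal beta-tubulin on chromosome 8, 43.3%, although fewer than 500 bp of Tubb3 lie outside other annotated genes. The very long Rbfox1 had 0.03% (0.24% and 0.63% in replicates 1 and 2) and Nrxn3 0.15% (0.20% and 0.34%). The list lay at percentile 99.5, and at 90.5 without matching on gene length, where it no longer stood apart.

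In the lists of neuronal subtypes, values in brackets are those of replicates 1 and 2. Of 15 projection neuron genes, 3 were marked at a median of 1.24%, and 2 in each replicate. Cux1 had 11.2% covered and Tbr1 10.6% (4.82% and 8.29%), so Tbr1 was marked in neither replicate's own list, and Fezf2 and Neurod1 had 0%. In bases of Cux1 outside other genes, 2.52% was covered. Of 12 GABAergic interneuron genes, Gad1 at 10.3% was the marked member, against 2 marked genes in replicate 1 and 3 in replicate 2. Gad2 had 8.54% (12.2% and 6.13%), Arx 0% and Dlx1 0% (0% and 3.03%). Of 12 striatal neuron genes, 0 were marked, with Meis2 at 3.49% (5.01% and 5.40%), Foxp1 at 1.15% (1.26% and 2.79%, and 1.89% in bases outside other genes), and Drd1 and Drd2 at 0%.

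Among progenitor and glial genes, few were marked, and values in brackets are again those of replicates 1 and 2. Of 16 neural progenitor genes, Foxg1 and Notch1 were marked, against 3 genes in each replicate's own list, and Eomes and Emx2 had 0%. Foxg1, the forebrain transcription factor on chromosome 12 from 49382660 to 49386861, had 23.0% covered and 21.4% ± 2.10 over the replicates (SD, n = 2), but 2.31% in bases outside other genes. Notch1 on chromosome 2 had 14.3%. Of 9 astrocyte genes, S100b was marked at 11.3% (11.2% and 8.94%), entirely in bases shared with another gene. Sparcl1 had 9.56% (9.92% and 11.5%), Aldoc 0% and Aldh1l1 0% (0% and 0.20%), and replicate 2 alone marked 2 of the 9. Of 10 oligodendrocyte lineage genes, Cnp was marked at 65.7%, with 39.2% in bases outside other genes. Mog had 4.91% (6.11% and 8.36%), Mag 0% and Cspg4 0% (0% and 1.00%). Of 12 microglia genes, Cx3cr1 at 16.01% and Hexb at 11.9% (11.1% and 7.25%) were marked, both with 0% in bases outside other genes, and Aif1 and C1qa had 0%, with 1 of the 12 marked in replicate 2. Of 10 immediate early genes, Npas4 at 27.6% (16.9% and 16.4%) and Nr4a1 at 12.6% (6.12% and 15.6%) were marked, and Arc and Egr1 had 0%, with 1 of the 10 marked in replicate 1.

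No gene was marked among 11 endothelial and mural genes such as Cdh5 or 9 erythroid genes such as Gata1 and Alas2. The 10 meningeal and choroid plexus genes, such as Col1a1, held no marked gene either. The share of each cell type in the tissue was not measured. Lists of other tissues, with 11 hepatocyte genes such as Afp and 13 striated muscle genes, held no marked gene. Nor did 10 midbrain and hindbrain patterning genes such as En1 and En2. In the muscle list, Ttn had 2.54% and Ryr1 0.40% (0.17% and 1.03% in replicates 1 and 2). Alas2 had 1.78% and 3.61% in the replicates' own lists. No gene was marked among 39 Hox genes such as Hoxa1, 105 keratin genes such as Krt10 or 40 replication-dependent histone genes such as Hist1h1a. The 1093 olfactory receptor genes, such as Olfr10, and 327 vomeronasal receptor genes, such as Vmn1r1, held none as well. In each of these families 0 members carried a replicated peak. Sequence uniqueness of these families is not given here, so their 0% cannot be read as absence of the mark.

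By medians, 7 of 28 lists stood apart, all above. The 18 lists with a median of 0% ranked only by their ties with random lists at 0%, at percentiles of 15.7 or more. By means, 20 stood apart, 6 above and 14 below. The 14 were the interneuron, striatal, progenitor, endothelial and mural, erythroid, meningeal, hepatocyte, muscle, midbrain and hindbrain, Hox, olfactory, vomeronasal, keratin and histone lists, with percentiles from 0 to 1.26.

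Lists of genes with special modes of regulation gave mixed values. Of 57 clustered protocadherin genes, which encode adhesion molecules, 21 were marked at a median of 3.58%, with Pcdhgc5 on chromosome 18 at 36.5% and Pcdhgc4 at 30.5%, and Pcdhb1 and Pcdhb10 at 0%. The list lay at percentile 99.8, but at 65.1 by the mean and at 93.7 without matching on gene length, where it no longer stood apart. Of its 57 genes, 56 have fewer than 500 bp outside other annotated genes, so coverage was not measured separately for their own bases. Of 17 imprinted protein-coding genes, 5 were marked at a median of 1.61% and percentile 62.4. Igf2r on chromosome 17 from 12682406 to 12769664 had 44.9% covered and 39.1% ± 1.11 over the replicates (SD, n = 2), and Impact on chromosome 18 had 34.9%, while Cdkn1c and Dlk1 had 0%.

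**Figure D3:**
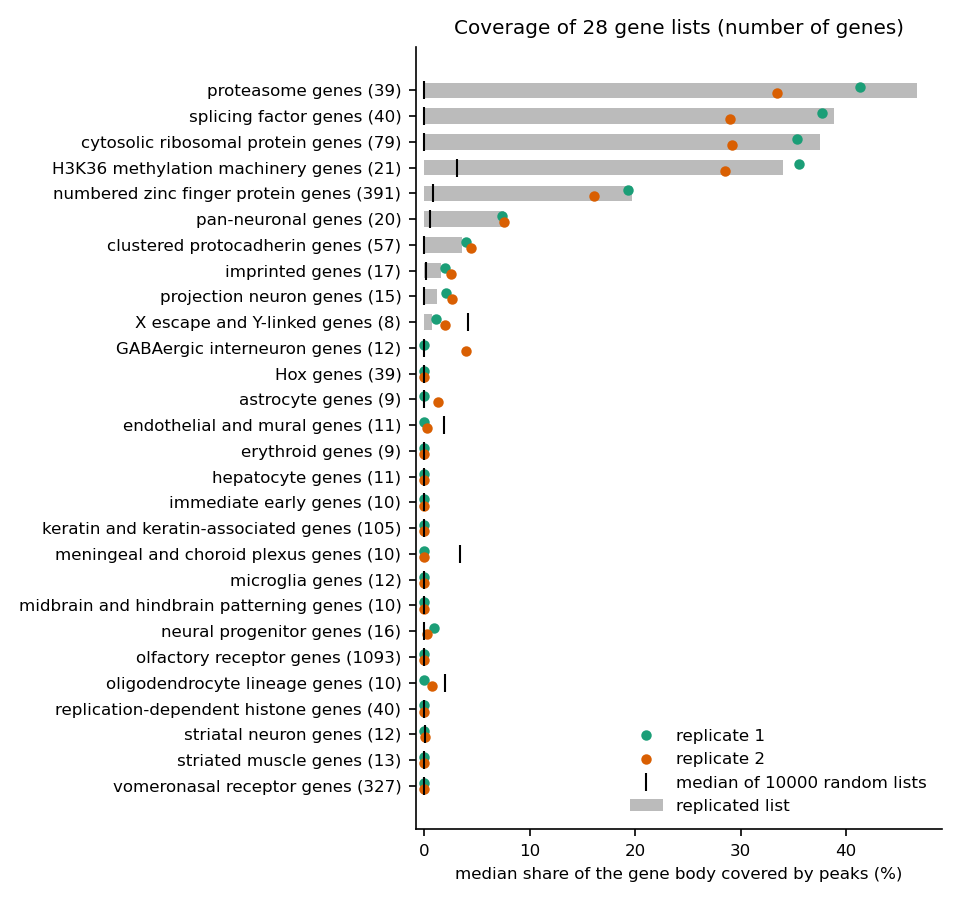
Median share of the gene body covered by peaks, in percent, for 28 gene lists with the number of genes in each, as bars for the replicated list, points for the 2 replicates and ticks for the median of 10000 random lists matched on gene length. Proteasome genes had the highest median (46.7%), and 18 lists had a median of 0%.

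Chromosomes were compared last, in tissue pooled from both sexes. On the autosomes 34.8% of protein-coding genes were marked, from 25.8% on chromosome 14 to 43.5% on chromosome 8. On the X, 53 of 923 genes (5.74%) were marked, and on the Y 0 of 179. Sequence uniqueness of the Y genes is not given here, so their 0 cannot be read as absence of the mark. In the pooled list the shares were 11.5% on the X and 39.6% on the autosomes. The share of each sex in the pools is not given in the sources used here, so values of X and Y are not scaled for copy number. The covered share of gene bodies on the X was 0.106 of that on the autosomes in the replicated list and 0.140 ± 0.015 over the replicates (SD, n = 2). In the list of genes that escape X inactivation or lie on the Y, Kdm5c, a demethylase on the X from 152233020 to 152274535, had 50.2% covered and 37.9% ± 14.4 over the replicates, and Eif2s3x, a translation initiation factor, had 34.9% and 28.7% ± 18.3. Ddx3y and Eif2s3y on the Y had 0%, with 1.57% of Ddx3y covered in replicate 2, and 3 of the 8 genes were marked.

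**Figure D4:**
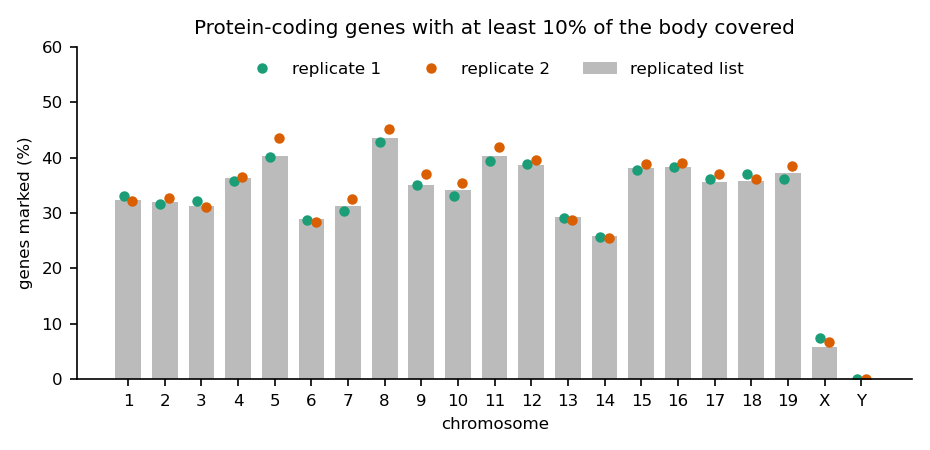
Protein-coding genes marked, in percent, by chromosome, with bars for the replicated list and points for the 2 replicates. The X stood at 5.74% and the Y at 0%, below the lowest autosome, chromosome 14, at 25.8%.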

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

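The counts in this part concern data outside the report's comparisons, and the noncoding genes named were chosen after their values were seen, apart from Meg3 and Mirg, which were written down with the imprinted genes. Both counts exceed 3, the limit set for data with no control samples, and neither was compared with chance. Of the genes for long noncoding RNAs that lie more than 5 kb from protein-coding genes, 27 had at least 10% of the body covered by replicated peaks. These were 0.565% of 4781 such genes, and peak bases in annotated genes outside protein-coding genes stood at 0.103 of the share in circular shifts. The list of replicate 1 gave 28 such genes and that of replicate 2 gave 51. Meg3, a maternally expressed imprinted RNA on chromosome 12 from 109541001 to 109571726, had 47.4% covered and 35.5% ± 8.25 over the replicates (SD, n = 2). Its neighbour Mirg had 46.1% and 33.7% ± 10.8. Among the others, Snhg17 on chromosome 2 had 63.7% and 58.1% ± 2.49, Lncppara on chromosome 15 had 39.3% and 35.7% ± 2.57, and Miat on chromosome 5 had 33.4% and 27.0% ± 6.26. Some of the 27 genes overlap each other, so they are not 27 separate places. Miat and Gm26953, on opposite strands, each had 5393 covered bp, and Gm26906 lies within the span of Meg3.

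The pooled list also held 20 peaks on unplaced and unlocalized scaffolds, with 17 in the list of replicate 1, 13 in that of replicate 2 and 4 in the replicated list. They lie outside the chromosomes on which genes were compared. No explanation was weighed for either count.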

How the results depend on the processing

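Leaving out first and last exons together, asking for overlap in both replicates and the X to autosome ratio of each replicate were tests chosen after seeing the data. The genic share, the ratio between gene ends, the overlap of the replicates and the number of marked genes kept their direction and their side of the threshold, or stayed within 1.5 times, under the alternatives run for each. Of the main values under alternatives, 32 stayed the same and 13 moved. Of the percentiles of the 28 lists under alternatives, 178 stayed the same, 14 became stronger, 3 became weaker and 1 reversed. Here the same means only that a list stayed on its side of the limits for standing apart. Projection neuron genes, for example, counted as the same at percentiles of 84.5 in the main setting, 42.3 with the 50000 strongest peaks and 9.03 by the mean. The 178 include lists whose medians rank only by ties with random lists, where an unchanged label says nothing about stability.

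The exon to intron ratio was 1.62 without first exons and 1.79 without first and last exons, and ranged from 1.81 to 1.95 with either replicate alone. In the 2 settings without exons, the intron share was 36.2% in 6992 genes, against 28.4% in the main setting. The exon share was higher as well, at 58.9% and 64.8% against 54.6%, so the ratios fell because the intron share rose more. The intron bases compared were thus not those of the main setting. The lower ratios therefore cannot be read as an effect of the exons left out. With means in place of medians 20 lists stood apart instead of 7, because a list with a median of 0% ranks only by its ties with random lists at 0%, and all 14 lists below by the mean had that median. The percentile of protocadherin genes came out at 22.6 in bases outside other genes and is counted as reversed, but it rests on 1 of 57 genes, since the others have fewer than 500 bp of such bases, and so says nothing about the list. The share of replicate 1 peaks found in replicate 2 was 70.6% at a −log10 q of at least 2, 54.9% for the 50000 strongest peaks and 53.0% with 50% of the peak's length. The pooled peaks kept were 62.1% at the stricter −log10 q and 36.6% with 50% of the length in both replicates. The correlation of gene-body coverage was 0.946 at the stricter −log10 q and 0.876 for the strongest peaks. The X to autosome ratio ranged from 0.129 to 0.151 with either replicate alone. Apart from the ties at 0%, the cause was not tested. Read depth is unknown, so what it limits was not tested.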

Other observations

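The tests below had their bounds fixed before their values were computed, but the patterns were noticed in the same data, and the genes named here outside the lists were chosen after their values were seen. Among noncoding genes of imprinted regions, Rian on chromosome 12 had 15.2% covered and 16.9% ± 1.28 over the replicates (SD, n = 2). Airn had 1.02% covered (0.84% and 1.57% in replicates 1 and 2), Kcnq1ot1 0.46% (0.84% and 1.39%) and H19 0%. Xist had 0% in the replicated list and 2.88% in replicate 1. Of replicated peaks, 45 lay more than 10 kb from any annotated gene, and the run with the most peaks, 6, lay on chromosome 5 from 104582139 to 104587435, with BC005561 as the nearest coding gene. On the X, Flna had 60.9% of its body covered, Maged1 54.4% (35.3% and 48.1% in replicates 1 and 2) and Hcfc1 52.2%. Eif2s3x had 41.6% covered in replicate 1 and 15.8% in replicate 2, and Kdm5c had 48.1% and 27.7%.

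The first pattern weighed was the low share of marked genes on the X. An X poor in generally used genes is argued against as the whole cause, since among general complexes 7 of 32 X-linked genes (21.9%) and 632 of 799 autosomal genes (79.1%) were marked (Fisher's exact p = 2.46e-11, over genes and not replicates). The X to autosome ratio of the percent marked was 0.277 among these complexes (95% interval 0.139 to 0.490). Reads mapping to several places are argued against as the whole cause as well. Among genes with at least 95% unique 31-mers the X to autosome ratio of the percent marked was 0.229 (95% interval 0.159 to 0.325). Over all coding genes the same ratio was 0.165, so a part played by gene content or by mapping is not excluded. A weaker signal on the X that falls short of the caller's threshold may still contribute. With peaks of at least 2 times the 5th percentile of enrichment, 9.74% of autosomal genes were marked. With all replicated peaks the shares were 34.8% on the autosomes and 5.74% on the X. That minimum is a simulated setting, and the value lies between the bounds set for a cause and for no effect. Median enrichment of replicated peaks was 3.32 on the X and 3.81 on the autosomes. In replicate 1 the medians were 3.09 and 3.32, and in replicate 2 they were 3.18 and 3.50. No biological explanation was tested.

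The next pattern was the share of numbered zinc finger genes among the strongest peaks, 8.40% of the 1000 strongest against 1.95% of all replicated peaks. The pattern concerns 84 of 2034 zinc finger peaks. Median enrichment was 3.88 in all zinc finger peaks and 3.79 in other peaks. Reads shared between paralogs are argued against as the whole cause, since the ratio of these shares was 4.29 (95% interval 3.45 to 5.33) for peaks with at least 95% unique 31-mers. A low control value is argued against as the whole cause as well, since the ratio was 3.42 (2.70 to 4.31) for peaks on the grid of equal steps in enrichment. Over all replicated peaks the ratio was 4.30, so a part played by the control value is not excluded. No biological explanation was tested.

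The last pattern was the higher coverage of exons than of introns, pooled over marked genes. The 100-bp windows were pooled too, so differences between genes were not held fixed. Repeats in introns are argued against as the whole cause, since the ratio in repeat-free windows was 1.89, with 1.84 in replicate 1 and 1.92 in replicate 2. In all windows the ratio was 2.05. GC content alone is argued against too as the whole cause, with a ratio of 1.88 after weighting repeat-free windows by it. The position of exons nearer the 3' end may account for part of the difference, since weighting by position lowered the ratio to 1.48. This value lies between the bounds set for a cause and for no effect. Weighting by GC content and position together gave 1.44, with 1.46 in replicate 1 and 1.43 in replicate 2. No bounds were set for the joint weighting. No biological explanation was tested.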
